A study of Mus musculus with 10 samples.

How the data were processed

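RNA was measured by sequencing in 10 libraries of tissue from the mouse cochlea, 5 labelled euthyroid and 5 labelled hypothyroid. Per the labels, the tissue was the outer sulcus, a strip of epithelium on the lateral side of the cochlear duct, dissected along with the spiral ligament beneath it. It came from C57BL/6J mice at postnatal day 10. Per the labels' protocols, pregnant mice drank vehicle or water with antithyroid agents from embryonic day 17, and treatment went on through lactation until postnatal day 10. The agents were methimazole at 0.05% and, as its monohydrate, sodium perchlorate at 1.0%, with sucrose at 5.0%. Methimazole blocks the synthesis of thyroid hormone and perchlorate blocks the uptake of iodide by the thyroid. The extraction text in the same labels speaks of articular cartilage of the femoral head at postnatal day 22. Every other label names the cochlea at postnatal day 10. The inner ear genes Otor, Otos and Coch had means of 5479, 3906 and 2868 CPM in the euthyroid libraries, and Otor had 6060 CPM in the hypothyroid ones, so the tissue was taken to be the cochlea. The age was taken from the labels and could not be tested.

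Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, copied with random hexamers and sequenced as single-end reads of 50 bases on a BGI instrument. Whether the libraries kept the strand of the RNA was not stated, so reads of overlapping or antisense genes could not be told apart. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 were used with genome build GRCm38.p6, and the role and order of these tools were not given. The deposited table held expected counts per gene and library, which RSEM estimates by dividing reads among genes and which need not be whole. Reads of near-identical copies such as Bglap and Bglap2, Hba-a1 and Hba-a2, or Hbb-bs and Hbb-bt may have been split between them, so single values of these genes were uncertain. Per the file headers and the values, the authors also deposited a scaled signal, which is the estimated count rounded up to a whole read and multiplied by 1 factor per library. Those factors ran from 1.049 to 1.117 in euthyroid and from 0.893 to 0.933 in hypothyroid libraries. After division by the factor, 100% of the values in each library were whole within 0.001. The authors deposited FPKM and TPM values, which adjust for gene length and library total, per the file headers. The authors' group means in the table were not used here.

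The expected counts were rounded to the nearest whole number. Genes with too few counts for a test were removed with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 14862 of 18725 genes. Library composition was adjusted with TMM factors. These averaged 0.912 in euthyroid and 1.10 in hypothyroid libraries, so scaling raised euthyroid values relative to hypothyroid values when compared with scaling by library size alone. Differences between groups were tested with edgeR's quasi-likelihood test (robust fit, group as the only term, two-sided) and Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 of hypothyroid minus euthyroid. SE is an approximate standard error, the absolute log2 fold change divided by the square root of the F statistic of the test. Levels are in CPM, computed by edgeR with the TMM-adjusted library size, as mean ± SD over 5 libraries. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.

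Library totals ran from 19298145 to 20063961 counts. Genes under the count filter were left out of the test per gene, and of these Dio3 is given by its counts and 4 early hair cell genes by their sum. Where a group had no count for a gene, the fold is given as a lower bound against 3 counts over the whole group. With 1 to 3 counts the ratio has a 95% interval from the exact binomial distribution, and both bounds cover counting error only. Over the 20 pairs of libraries within a group, the mean chi-square per gene lay between 5.41 and 16.0, above the value of sampling noise alone, so no library was treated as a duplicate. The labels number the libraries within each group but do not say whether each came from a separate animal. P-values therefore measure only the spread among these libraries, part of which may be technical. The agents were given through the mothers, and the mother or litter of each library was not known here. A litter effect could therefore not be told apart from the treatment.

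Before the data were examined, 34 gene lists of pathways and cell types were fixed, together with the rule for the genes to be named. The rule took the 10 higher and 10 lower genes with the largest change among genes with adjusted p under 0.05, a mean of at least 5 CPM, no overlap between the groups and an assigned symbol. It added the 3 members of each list with the smallest adjusted p, and 12 further genes named in advance: Thra, Thrb, Dio2, Dio3, Hr, Klf9, Slc26a4, Anxa1, Kcnj16, P2rx2, Lgr5 and Epyc. Aqp5, Coch, Crym, Espn, Otof, Otor, Otos, Slc26a5, Stac2 and Tmc1 fall outside the rule and were chosen after their values were seen. So were Ceacam16, Col11a1, Col11a2, Otog, Otogl, Tecta and Tectb, which are not among the single genes compared over the alternatives. Some genes that the rule names are not reported here. Lists with at least 3 tested genes were tested with limma's camera, which compares a list with the other genes, on log2 CPM (prior count 2) with the correlation between genes preset to 0.01. The test was repeated with a correlation estimated per list, and with fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. The mean log2 CPM of each list per library was compared with an exact two-sided permutation test over the 252 arrangements of the libraries, whose smallest possible p is 0.00794.

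Alternatives set in advance were RLE, upper quartile and no composition factors, no filter and a filter of 1 CPM in 5 libraries, DESeq2, limma-voom, a term for the replicate number, removal of each library in turn, removal of haemoglobin genes, limma on log2(FPKM + 1), the other gene set tests, and a test against a fold of 1.2. Whole reads recovered from the scaled signal, limma on log2(TPM + 1), a covariate of Y-linked genes and removal of each library from the list means were added after the data were seen. Both limma fits used genes with a mean of at least 1. The main test was checked on simulated counts for 14747 genes in 5 against 5 libraries with known changes. It recovered 54% of 50 genes changed 1.25-fold, 82% of 50 changed 1.5-fold, 94% of 50 changed 2-fold and 100% of 50 changed 4-fold. There were 8 calls among 14532 unchanged genes. Only these 200 genes, changed in both directions, and a list of 15 genes were altered. In the data 71.8% of tested genes changed and library composition differed between groups. The simulation therefore did not check how the scaling affects the calls.

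Gene identifiers in the table were NCBI gene numbers. Of 18725 identifiers, 18669 matched the RefSeq annotation of GRCm38.p6, 18359 of them with the same symbol, and coordinates were taken from that annotation as the full gene span.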

Results

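The series compared the outer sulcus and adjoining spiral ligament of mice made hypothyroid from late gestation with those of euthyroid mice, at postnatal day 10. The outer sulcus holds the root cells, whose processes reach into the spiral ligament, and the question was how the lack of thyroid hormone alters its development. The 5 euthyroid libraries held 19781921 to 20063961 estimated counts and the 5 hypothyroid libraries 19298145 to 19407592. The 20 most abundant genes took 14.6% ± 0.476 of counts in euthyroid and 9.20% ± 0.265 in hypothyroid libraries (SD, n = 5 each). Col2a1, the collagen of cartilage, alone took 2.95% ± 0.128 and 1.37% ± 0.038 (SD, n = 5 each). Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.986 to 0.992 within groups and 0.910 to 0.930 between groups.

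**Figure D1:**
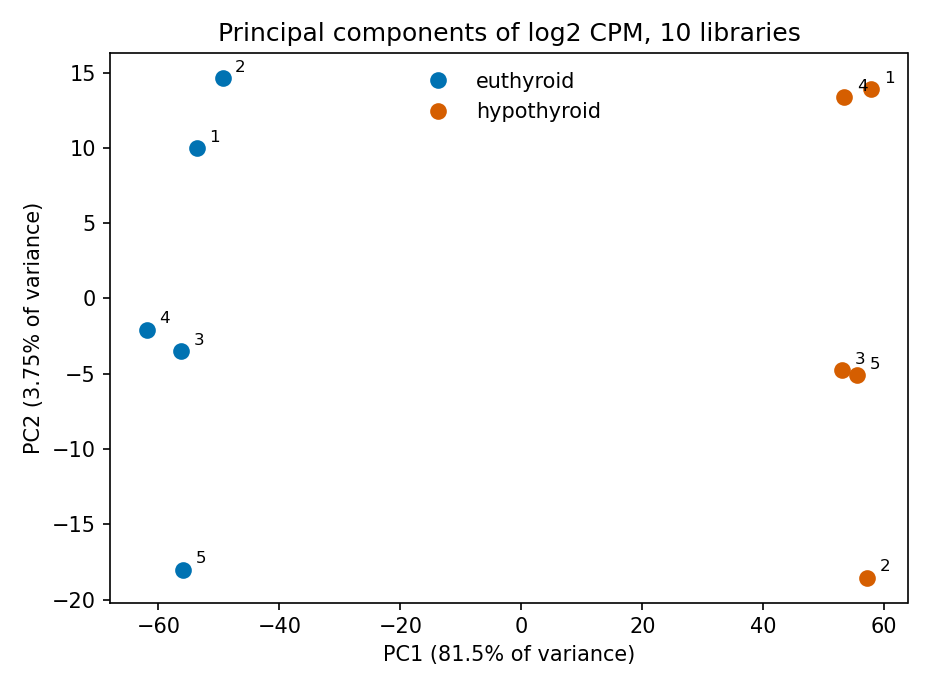
Principal components of log2 CPM over 14862 genes, with PC1 on the horizontal and PC2 on the vertical axis (arbitrary units). Each point is 1 library, numbered by replicate, and the groups lie apart on PC1, which holds 81.5% of the variance.

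Of the 14862 genes tested, 5603 were higher and 5064 lower in the hypothyroid libraries. Among genes with a mean of at least 5 CPM, no overlap between the groups and an assigned symbol, the largest increases were in Agtr2, a receptor for angiotensin II, Wfdc18, the tolloid-like protease gene Tll2, Lyve1, a hyaluronan receptor of lymphatic endothelium and some macrophages, Cdh26, Nell1, the laminin gene Lama1, Shisa3, the tight junction gene Cldn6, and Gdpd2. By the same limits the largest decreases were in the osteocalcin genes Bglap2 and Bglap, in Ocm, which encodes a calcium-binding protein of outer hair cells, in Tmprss9, Umodl1, the type IV collagen gene Col4a3, the osteocyte gene Sost, the bone matrix gene Mepe, the bicarbonate transporter gene Slc4a10, and Corin. Agtr2 rose from 0.638 ± 0.196 to 27.5 ± 2.46 CPM (SD, n = 5 each; log2 fold change 5.41, SE 0.14, edgeR adjusted p = 1.35e-13). Tll2 rose from 5.91 ± 1.62 to 183 ± 7.89 CPM and Lyve1 from 1.42 ± 0.379 to 41.7 ± 15.01 CPM. Tmprss9 fell from 317 ± 26.8 to 0.482 ± 0.191 CPM, a difference of 651-fold. Col4a3 fell from 1273 ± 92.2 to 5.18 ± 0.5995 CPM (246-fold, log2 fold change -7.94, SE 0.09, edgeR adjusted p = 1.48e-17). Bglap2 had 2900 counts over the euthyroid libraries and 0 over the hypothyroid ones, at least 1132-fold lower, although its reads may be shared with Bglap. Bglap had a log2 fold change of -7.80, or -9.95 without hypothyroid replicate 3. Slc4a10 fell 121-fold, from 413 ± 119 to 3.41 ± 1.33 CPM.

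In total 10667 genes, 71.8% of those tested, passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and 2551 of them changed at least 2-fold, 1375 upward and 1176 downward. At least 8-fold changes were seen in 82 higher and 169 lower genes. The groups did not overlap in 8602 genes (57.9%), where chance gives 0.794% of genes. The balance of directions depended on scaling: 52.5% of changed genes were higher as reported, 74.7% with library sizes alone (8650 higher and 2928 lower) and 62.5% with upper quartile factors. Limma on FPKM and TPM, which also changes the test and filter, gave 74.0% and 71.3%. The median log2 fold change of all genes was 0.04 as reported and 0.30, 0.15, 0.24 and 0.23 in those 4 alternatives, in that order, so the direction of changes smaller than this shift was not fixed. The labels do not say whether the libraries came from separate animals, and their litters were not known here.

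Of the 34 gene lists, 4 were higher and 7 lower than the other genes by camera (adjusted p under 0.05, preset correlation). With an estimated correlation 0 lists passed after adjustment, while 15 had an unadjusted p under 0.05 with the preset correlation, and fry gave 27. Of 100 splits of the libraries into 5 and 5, 15 gave as many lists by camera, the real split included. Camera's adjusted p-values with the preset correlation may therefore be too small for single lists as well. Means of 28 lists differed between groups by the exact permutation test. That test does not compare a list with other genes, and 57.9% of single genes did not overlap between the groups either. Most list means could therefore be foreseen to differ, and the number is no result about these lists in particular. Adjusted over the list alone, the counts of higher and lower genes equalled those over all genes in all lists but 3, which are named with their counts.

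**Figure D2:**
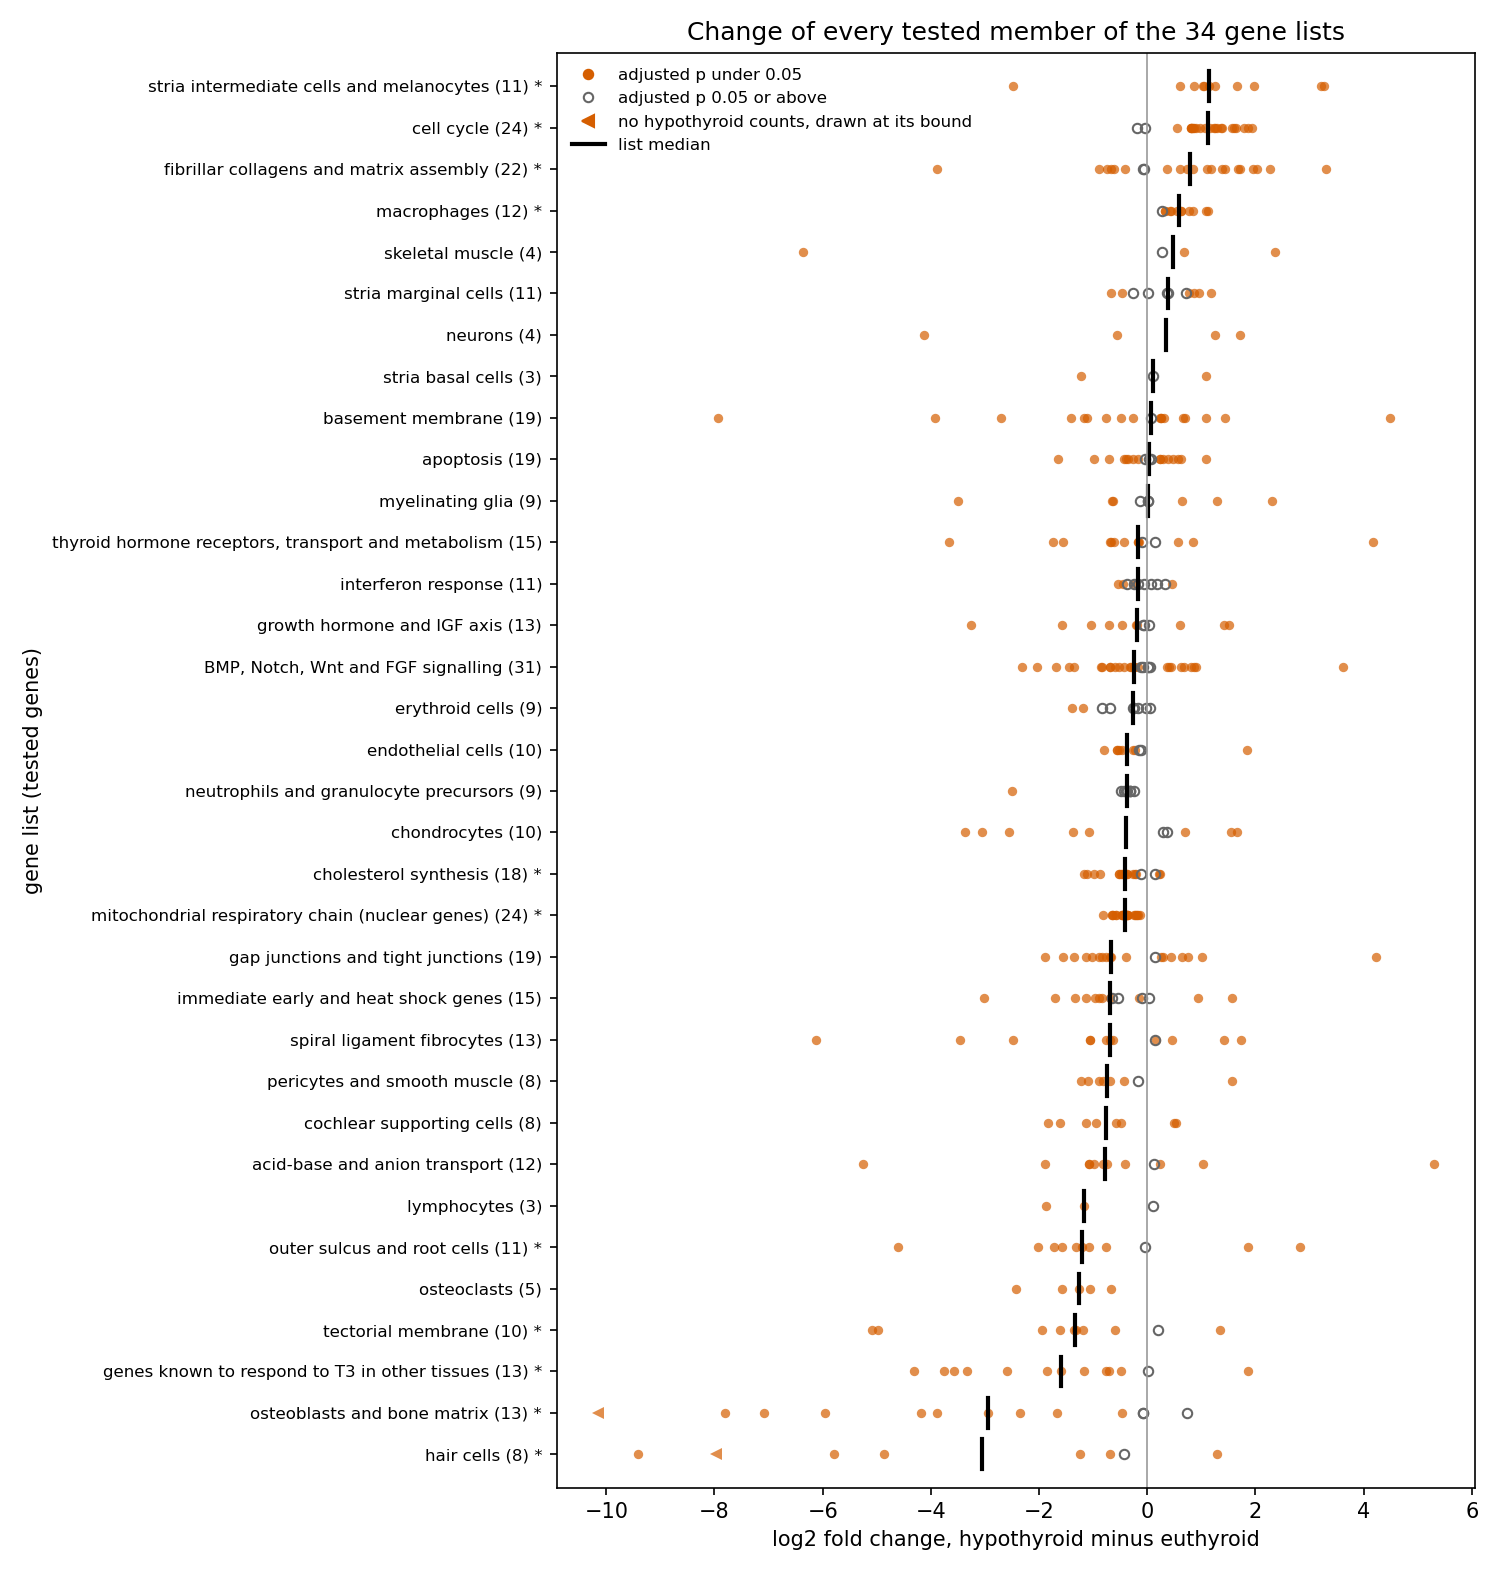
Log2 fold change (hypothyroid minus euthyroid, horizontal axis) of each tested member of the 34 gene lists (vertical axis, number tested in brackets). Filled points passed adjusted p 0.05, open points did not, triangles are genes without hypothyroid counts drawn at their bound, bars are list medians, and stars mark the 11 lists past camera adjusted p 0.05, from hair cells at a median of -3.05 to stria intermediate cells at 1.15; camera calls of this kind were all lost with an estimated correlation.

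Thyroid hormone target genes were lower in the hypothyroid tissue. Of 13 genes known to respond to triiodothyronine (T3) in other tissues, 11 fell, 1 rose and 1 did not pass (median log2 fold change -1.59, camera adjusted p = 0.000235, and adjusted p = 0.481 with an estimated correlation). Hr, a nuclear receptor corepressor gene and textbook T3 target, fell 19.8-fold from 111 ± 8.57 to 5.58 ± 0.309 CPM (SD, n = 5 each; edgeR adjusted p = 7.84e-16). Klf9, a Krüppel-like transcription factor gene induced by T3, fell 11.8-fold from 279 ± 61.6 to 23.6 ± 8.29 CPM. The mitochondrial glycerol phosphate dehydrogenase gene Gpd2 fell 6.07-fold and the clock output gene Dbp 3.61-fold. Stac2 was the member that rose, with a log2 fold change of 1.86.

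Genes for the handling of thyroid hormone moved both ways. Of 15 receptor, transport and metabolism genes, 3 rose, 10 fell and 2 did not pass (camera adjusted p = 0.142). Slco1c1, which carries thyroxine into cells, fell 12.7-fold from 1121 ± 98.5 to 88.6 ± 10.9 CPM, and the transporter gene Slc16a10 fell 2.95-fold. Crym, which encodes a cytosolic protein that binds T3, rose from 36.4 ± 8.20 to 657 ± 74.9 CPM (log2 fold change 4.17). The receptor gene Thra rose 1.80-fold, from 174 ± 7.34 to 313 ± 13.0 CPM, and Thrb fell 1.61-fold, from 99.6 ± 7.02 to 61.9 ± 5.85 CPM. Dio2, whose product makes T3 from thyroxine, fell 1.53-fold from 914 ± 116 to 597 ± 109 CPM (edgeR adjusted p = 0.00156). Dio3, whose product inactivates T3, had 39 counts over the euthyroid and 0 over the hypothyroid libraries, at least 15.2-fold lower, but was too low to be tested. With library sizes alone 5 members were higher and 6 lower, and the list median turned from -0.17 to 0.09.

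**Figure D3:**
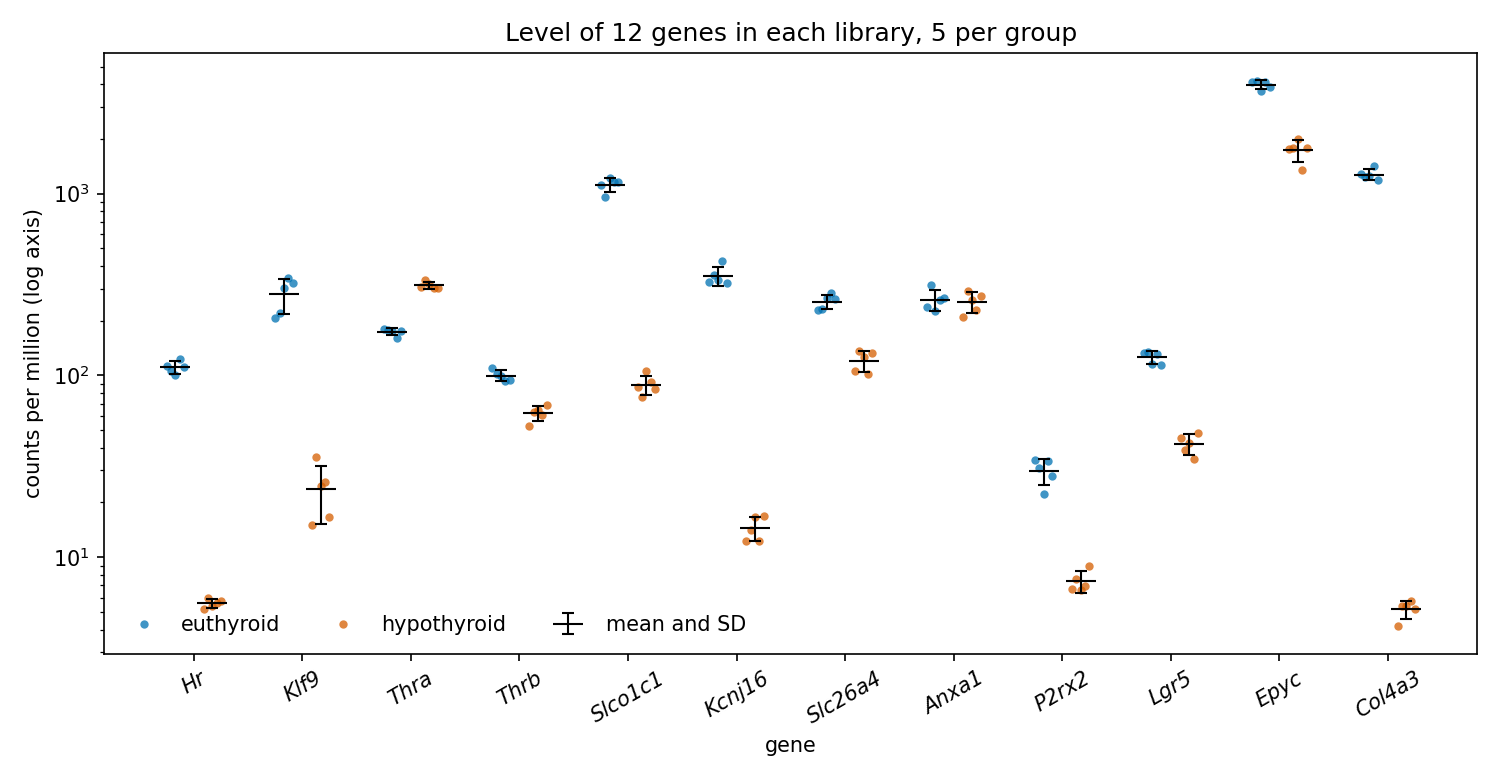
CPM (vertical log axis) of 12 genes (horizontal axis) in each of the 5 euthyroid and 5 hypothyroid libraries, as points, with mean and SD as bars. Hypothyroid libraries lie below all euthyroid ones in 10 genes and above them in Thra, while Anxa1 overlaps (261 ± 34.7 against 253 ± 33.5 CPM).

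Root cell and outer sulcus genes were mostly lower. Of 11 such genes, 8 fell, 2 rose and 1 did not pass (median -1.197, camera adjusted p = 0.0285, and adjusted p = 0.481 with an estimated correlation). The potassium channel gene Kcnj16 fell 24.4-fold, from 353 ± 42.5 to 14.5 ± 2.22 CPM (SD, n = 5 each; log2 fold change -4.61, SE 0.11, edgeR adjusted p = 2.11e-12). Slc26a4, the gene of the anion exchanger pendrin, fell 2.11-fold from 255 ± 23.5 to 121 ± 15.9 CPM. The ATP-gated channel gene P2rx2 fell 4.05-fold, Lgr5, a receptor gene of the Wnt pathway, 2.99-fold, Epyc, a proteoglycan gene, 2.29-fold from 3978 ± 220 to 1735 ± 235 CPM, and Sparcl1 2.49-fold. Dpp10 rose 7.09-fold and Aqp5, a water channel gene, also rose (log2 fold change 1.86). Anxa1 differed by less than the spread between libraries (log2 fold change -0.04, adjusted p = 0.715), and with library sizes alone its value was 0.22 (adjusted p = 0.0817; 0.0723 to 0.945 over all alternatives). Bone and hair cell genes were lower in the same libraries (list medians -2.95 and -3.05), and melanocyte and macrophage genes were higher (1.15 and 0.59). On GRCm38.p6, Kcnj16 spans chromosome 11 from 110968033 to 111027968, Slc26a4 chromosome 12 from 31519814 to 31560055, Slco1c1 chromosome 6 from 141524354 to 141570177, and Hr chromosome 14 from 70554056 to 70573548.

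In the spiral ligament, 8 of 13 fibrocyte genes fell, 4 rose and 1 did not pass (median -0.70, camera adjusted p = 0.178, 0.0209 with library sizes alone, and 0.0209 to 0.206 over the alternatives). Atp1b1, a subunit of the sodium pump, fell 5.59-fold from 1874 ± 102 to 336 ± 31.2 CPM. Otos and Coch, genes of secreted proteins of the ligament, fell from 3906 ± 766 to 56.1 ± 20.7 and from 2868 ± 660 to 261 ± 37.6 CPM. Tgfbi rose 3.32-fold and the water channel gene Aqp1 2.68-fold. Otor stayed among the abundant genes at 5479 and 6060 CPM, and its adjusted p was 0.109, 0.000158 with library sizes alone, and 0.0441 and 0.0342 without hypothyroid replicate 2 or 4 (0.000158 to 0.304 over the alternatives).

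Ion transport and junction genes did not pass as lists. Among 12 acid-base and anion transport genes 8 fell, 3 rose and 1 did not pass (camera adjusted p = 0.0778, 0.00892 with library sizes alone, and 0.00210 to 0.101 over the alternatives). Car2, a carbonic anhydrase gene, fell 3.71-fold from 340 ± 43.0 to 91.7 ± 7.43 CPM, and Slc9a3r1, a scaffold gene of transporters, 1.67-fold. Atp6v1b1, a proton pump subunit gene, rose 39.2-fold from 0.0659 ± 0.0458 to 2.84 ± 0.258 CPM, with only 6 counts over the euthyroid libraries. Among 19 gap and tight junction genes 11 fell, 7 rose and 1 did not pass (camera adjusted p = 0.210, 0.0279 with library sizes alone, and 0.0279 to 0.281 over the alternatives). Cldn6 rose 18.7-fold, whereas Cldn9 fell 2.57-fold.

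Extracellular matrix genes moved both ways. Of 22 fibrillar collagen and matrix assembly genes, 14 rose, 6 fell and 2 did not pass (median 0.80, camera adjusted p = 0.0476, and adjusted p = 0.498 with an estimated correlation). Periostin (Postn) rose 9.92-fold from 29.5 ± 3.17 to 293 ± 31.3 CPM, elastin (Eln) 3.88-fold and biglycan (Bgn) 2.70-fold. The list was no longer called with library sizes alone (adjusted p = 0.183), with upper quartile factors (0.0870), on FPKM (0.168) or TPM (0.155), with the stricter filter (0.0514), with the replicate block (0.0515), with the Y-linked covariate (0.0548) or without hypothyroid replicate 3 (0.0501), and ranged from 0.0237 to 0.183 over the alternatives. Basement membrane genes split evenly, with 9 of 19 higher, 9 lower and 1 not passing (camera adjusted p = 0.639, direction down, median 0.07, mean -0.54). Col4a4, a partner of Col4a3 in type IV collagen, fell 15.2-fold from 396 ± 24.2 to 26.0 ± 5.24 CPM, and Lama1 and Lama4 rose 22.5-fold and 2.12-fold. Col4a3 lies on chromosome 1 of GRCm38.p6 from 82586921 to 82722059.

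Of 10 genes of the tectorial membrane, the gel above the hair cells, 8 fell, 1 rose and 1 did not pass (median -1.33, camera adjusted p = 0.00334, and adjusted p = 0.481 with an estimated correlation). The abundant type IX collagen genes fell, Col9a3 3.07-fold from 6668 ± 369 to 2170 ± 84.8 CPM, Col9a2 2.56-fold and Col9a1 2.48-fold. The type XI collagen genes Col11a1 and Col11a2 fell 3.87-fold and 2.285-fold. These collagens are also cartilage components. The other members differed in direction. Ceacam16 fell 34.2-fold, Tectb 31.7-fold (20.4 ± 25.9 against 0.637 ± 0.459 CPM) and Otogl 1.51-fold. Tecta rose 2.53-fold (edgeR adjusted p = 0.000118), and Otog did not pass (edgeR adjusted p = 0.451). Among 10 chondrocyte genes 5 fell, 3 rose and 2 did not pass (median -0.39, camera adjusted p = 0.305, 0.0405 with library sizes alone, and 0.0248 to 0.389 over the alternatives). Col2a1 fell 2.59-fold from 32370 ± 2003 to 12480 ± 392 CPM, Chad 5.90-fold and Cnmd 2.11-fold.

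Bone matrix genes were lower. Of 13 osteoblast and bone matrix genes 10 fell, 0 rose and 3 did not pass (median -2.95, the same with Bglap2 at its bound; camera adjusted p = 0.000722, and adjusted p = 0.481 with an estimated correlation). Ibsp, the bone sialoprotein gene, fell 62.3-fold from 763 ± 128 to 12.3 ± 5.07 CPM, and Dmp1 18.1-fold. Mepe fell 136-fold and Sost 144-fold; without hypothyroid replicate 3 the log2 fold change of Mepe went from -7.09 to -7.75. With library sizes alone 9 bone genes were lower and 2 higher. All 5 tested osteoclast genes fell, Ctsk 2.09-fold, Acp5 5.39-fold and Mmp9 2.97-fold (camera adjusted p = 0.0710, 0.0362 without euthyroid replicate 2, 0.00876 with library sizes alone, and 0.00876 to 0.0922 over the alternatives).

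Hair cell genes were mostly lower, by very different amounts. Of 8 tested, 6 fell, 1 rose and 1 did not pass (median -3.05, the same with Slc26a5 at its bound; camera adjusted p = 0.0398, and adjusted p = 0.498 with an estimated correlation). Ocm fell 681-fold from 30.02 ± 13.3 to 0.0378 ± 0.0395 CPM, Strc, the stereocilin gene, 55.4-fold and Chrna10, an acetylcholine receptor gene, 29.3-fold. These genes had only 4, 8 and 7 counts over the hypothyroid libraries, so the size of these folds is uncertain. The folds come from the edgeR fit and can differ from the ratio of the means. Slc26a5, the outer hair cell motor gene, had 641 counts against 0, at least 250-fold lower. Otof fell 2.36-fold and Espn 1.60-fold, and Tmc1 did not pass (log2 fold change -0.42, adjusted p = 0.0804), except without euthyroid replicate 2 (0.0272) or 3 (0.0381) or hypothyroid replicate 2 (0.0444), in a range of 0.0272 to 0.491. Myo7a, a myosin gene, rose 2.46-fold from 12.6 ± 1.38 to 30.8 ± 3.01 CPM. The list was not called with the stricter filter (0.0733) or on FPKM (0.214, with only 3 genes tested), with a range of 0.00167 to 0.214 over the alternatives. Of 8 supporting cell genes 6 fell and 2 rose, among them Otoa (3.55-fold lower), Fgfr3 (3.06-fold) and Cdkn1b (1.49-fold). Its camera adjusted p of 0.0534 passed with library sizes alone (0.00876) and without any of 7 libraries taken singly, at 0.0487 (euthyroid replicate 2), 0.0209 (3), 0.0497 (5), 0.0352 (hypothyroid replicate 1), 0.0325 (2), 0.0361 (4) and 0.0353 (5), with 0.00180 to 0.0664 over all alternatives.

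In the stria vascularis, the epithelium that secretes endolymph, only the intermediate cell list of 3 was called. Of 11 genes of intermediate cells, which are melanocytes, 10 rose and 1 fell (median 1.15, camera adjusted p = 0.0215, and adjusted p = 0.525 with an estimated correlation). Gpr143 rose 3.15-fold from 1.88 ± 0.197 to 5.93 ± 1.55 CPM and Met 1.52-fold, whereas the potassium channel gene Kcnj10 fell 5.60-fold from 168 ± 16.0 to 29.98 ± 6.65 CPM. The call was lost with library sizes alone (adjusted p = 0.112), on FPKM (0.158) and on TPM (0.0830), with a range of 0.00855 to 0.158 over the alternatives. Of 11 marginal cell genes 4 rose, 2 fell and 5 did not pass (camera adjusted p = 0.726), with Shroom3 1.59-fold lower and Wnk2 1.38-fold lower. Of 3 basal cell genes Cldn11 rose 2.13-fold, Sox8 fell 2.35-fold and Nr2f2 did not pass (camera adjusted p = 0.896, direction up, median 0.11, mean -0.01). Nr2f2 had a log2 fold change of 0.11 (adjusted p = 0.0946), which passed without hypothyroid replicate 2 (0.13, 0.0466) and with library sizes alone (0.37, 6.72e-05), with adjusted p up to 0.309 over the alternatives.

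Neuronal and glial lists showed no common direction. Of 4 tested neuronal genes 2 rose and 2 fell (camera adjusted p = 0.896, direction up, median 0.34, mean -0.43). Syt1 rose 3.28-fold and Tubb3, a neuronal tubulin gene, fell 17.6-fold from 12.2 ± 2.19 to 0.698 ± 0.969 CPM. Its log2 fold change went from -4.14 to -5.47 without hypothyroid replicate 3, and Nefh, a neurofilament gene at 0.296 and 0.717 CPM, rose 2.38-fold. On FPKM and TPM, where only 2 and 3 neuronal genes were tested, the neuronal median was -0.38 and -0.14. Of 9 genes of myelinating glia 3 rose, 3 fell and 3 did not pass (camera adjusted p = 0.935, direction up, median 0.01, mean -0.07). Pmp22 fell 1.54-fold, and Cldn19 rose with a log2 fold change of 2.30, or 2.97 without euthyroid replicate 5. With RLE factors the glial median was -0.02.

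Macrophage genes were higher: 11 of 12 rose and 1 did not pass (median 0.59, camera adjusted p = 0.00730, and adjusted p = 0.481 with an estimated correlation). Mrc1 rose 2.13-fold from 58.8 ± 1.53 to 125 ± 20.05 CPM, C1qc 1.79-fold and Csf1r 1.47-fold. Other blood cell lists did not pass. Of 9 neutrophil genes only Mpo fell, with 0 lower when adjusted over the list alone (camera adjusted p = 0.258), and its adjusted p of 0.0257 rose to 0.0567, 0.0513, 0.0561 and 0.0535 without hypothyroid replicate 2, 3, 4 or 5 (0.00696 to 0.0592 over the alternatives). The log2 fold change of Mpo, -2.51, went to -1.58 without euthyroid replicate 3 and to -3.64 without hypothyroid replicate 1. Camp (-0.39, adjusted p = 0.114) passed without hypothyroid replicate 1 (0.0386, range 0.0386 to 0.624) and Lcn2 (-0.32, 0.0822) without euthyroid replicate 4 (0.0478, range 0.0478 to 0.757). Of 3 lymphocyte genes Cd3e and Cd79a fell (camera adjusted p = 0.420), and Cd79a did not pass without euthyroid replicate 3 (0.0632, range 0.00646 to 0.0632), while Cd79b did not pass (adjusted p = 0.782). Of 9 erythroid genes 2 fell, Epb42 among them, and 7 did not pass (camera adjusted p = 0.300, median -0.25, or 0.01 with library sizes alone). Rhag, with a log2 fold change of -0.69 (adjusted p = 0.0537), passed without euthyroid replicate 1 (0.0414) or 2 (0.0383) or hypothyroid replicate 2 (0.0279), in a range of 0.0279 to 0.205.

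Neither list of vessel genes passed. Of 10 endothelial genes 7 fell, 1 rose and 2 did not pass (median -0.37, camera adjusted p = 0.116), among them Tie1, 1.75-fold lower, Emcn, 1.38-fold lower, and Vwf, 3.59-fold higher. Of 8 pericyte and smooth muscle genes 6 fell, 1 rose and 1 did not pass (median -0.75), with Rgs5 2.34-fold, Kcnj8 2.12-fold and Pdgfrb 1.75-fold lower. The camera adjusted p of this list, 0.0509, was 0.00876 with library sizes alone and 0.0362, 0.0428, 0.0464, 0.0464 and 0.0460 without euthyroid replicate 2 or 5 or hypothyroid replicate 1, 4 or 5, in a range of 0.00172 to 0.0652. Of 4 skeletal muscle genes 2 rose, 1 fell and 1 did not pass (camera adjusted p = 0.700, direction up, median 0.48, mean -0.77). Tnnt3 rose 5.11-fold and Actn3 1.61-fold, and on FPKM, where only 2 of these genes were tested, the list median was -0.08. Pvalb had 188 counts against 2, a ratio of 110 after scaling with a 95% counting interval of 30.04 to 915. Both counts were in hypothyroid replicate 3, and without it the other 4 libraries had 0, at least 59.0-fold lower.

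Cell division genes were higher: 22 of 24 rose and 2 did not pass (median 1.118, camera adjusted p = 5.08e-05, and adjusted p = 0.481 with an estimated correlation). The replication helicase genes Mcm6, Mcm5 and Mcm7 rose 2.38-fold, 2.36-fold and 1.97-fold, Mcm6 from 17.5 ± 1.34 to 41.5 ± 5.17 CPM. Of 19 apoptosis genes 8 rose, 8 fell and 3 did not pass (camera adjusted p = 0.913, direction down, median 0.04, mean -0.05), and with library sizes alone 11 rose and 4 fell. Cdkn1a, a cell cycle inhibitor gene, fell 3.13-fold, Cycs, the cytochrome c gene, 1.64-fold, and Bcl2l11, which promotes apoptosis, rose 2.13-fold.

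All 24 nuclear genes of the mitochondrial respiratory chain fell, by a median of -0.41 on the log2 scale (camera adjusted p = 7.85e-06, and adjusted p = 0.481 with an estimated correlation). Cox5a fell 1.77-fold from 67.6 ± 3.78 to 38.3 ± 3.56 CPM, Cox8a 1.57-fold and Ndufs1 1.38-fold. With library sizes alone 15 were lower, 9 did not pass and the median was -0.15, and on FPKM 1 was higher and 16 lower. Of 18 cholesterol synthesis genes 14 fell, 2 rose and 2 did not pass (median -0.41, camera adjusted p = 0.00730, and adjusted p = 0.481 with an estimated correlation). Insig1 fell 2.17-fold, Hsd17b7 1.99-fold and Msmo1 1.83-fold. With library sizes alone 7 of this list were lower and 4 higher.

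Signalling lists held large changes in both directions. Of 31 BMP, Notch, Wnt and FGF genes 17 fell, 9 rose and 5 did not pass (camera adjusted p = 0.258), turning to 11 lower and 13 higher with library sizes alone, where the median went from -0.24 to 0.03. Sfrp2, a secreted Wnt modulator gene, rose 12.4-fold from 7.70 ± 1.06 to 95.3 ± 8.27 CPM, Hey1 fell 4.12-fold and Id2 3.22-fold. Of 13 growth hormone and IGF genes 7 fell, 3 rose and 3 did not pass (camera adjusted p = 0.339, median -0.20, or 0.07 with library sizes alone). Igf2 rose 2.84-fold from 437 ± 38.4 to 1241 ± 67.4 CPM while Socs2 fell 2.96-fold and Igfbp7 2.06-fold. Of 15 immediate early and heat shock genes 9 fell, 10 when adjusted over the list alone, 2 rose and 4 did not pass (camera adjusted p = 0.119, 0.0218 with library sizes alone, and 0.0218 to 0.175 over the alternatives). Ier2 fell 1.87-fold, and the heat shock genes Hspa1a and Hspa1b rose 2.96-fold and 1.91-fold. Of 11 interferon response genes 3 fell, 1 rose and 7 did not pass, with 2 lower and 0 higher when adjusted over the list alone (camera adjusted p = 0.574), and with library sizes alone 3 rose and 1 fell. Bst2 fell 1.45-fold and Oas1a 1.36-fold, the last not with library sizes alone (adjusted p = 0.248, range 0.00512 to 0.248).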

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

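Of 324 groups of 5 libraries examined, 13 held a library whose gap to its neighbour was large for the range of its group, where chance alone would give 16.2. Their number was therefore no larger than chance gives. The genes and lists are not independent, so this count cannot exclude a deviant library. Without hypothyroid replicate 3 the folds of Bglap, Pvalb, Tubb3 and Mepe moved 4.44, 3.94, 2.52 and 1.58 times. Mpo moved 1.9 and 2.19 times without euthyroid replicate 3 and hypothyroid replicate 1, and Cldn19 1.59 times without euthyroid replicate 5. No biological explanation was tested for the 13 flagged groups. The total of euthyroid replicate 1 was the highest of its group at 20.064 M counts (20063961), with the next at 19.854 M (19853833). The mean log2 CPM of the thyroid hormone receptor, transport and metabolism list stood apart in the same library at 6.986, with the next at 6.920. The list of genes responding to T3 was highest in euthyroid replicate 4 at 4.665, with the next at 4.516. In hypothyroid replicate 4 the stria basal cell list reached 7.224, above 7.035, and the pericyte and smooth muscle list 4.424, above 4.313.

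Single genes met the same criterion, all in log2 CPM. Thra was lowest in euthyroid replicate 4 at 7.34, Pmp22 lowest in hypothyroid replicate 5 at 6.68, and Vwf lowest in euthyroid replicate 1 at 2.15. Cldn19 was highest in euthyroid replicate 5 at 1.11, where the next library had -0.52, and Postn was highest in the same library at 5.14. Pvalb was highest in hypothyroid replicate 3 at -2.34, the only hypothyroid library with counts of this gene. Bcl2l11 was lowest in euthyroid replicate 2 at 3.94 and Ier2 highest in hypothyroid replicate 1 at 4.98.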

How the results depend on the processing

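The TPM, recovered-read, Y-linked and list-mean leave-one-out alternatives were chosen after the data were seen. The scaling changed the balance of directions: with library sizes alone 8650 genes were higher, 2928 lower and 17 lists passed. With limma on FPKM 2652 were lower and 1350 changed at least 2-fold, and on TPM 3115 were lower and 17 lists passed; these fits also differ in test, added constant and filter, and the cause was not tested. Of 11578 genes called with library sizes alone, 8716 were also called as reported, 8531 of them in the same direction. TMM factors differed between the groups, and which scaling is right was not settled. Col1a2 turned from -0.08 to 0.18 with library sizes alone and on FPKM and 0.14 on TPM. An estimated correlation left 0 lists and fry gave 27, and a test against a fold of 1.2 gave 7093 genes. DESeq2 gave 10586 genes and left 1 other gene with an adjusted p of NA. Limma-voom gave 10656 genes, RLE factors 10672, upper quartile factors 11055, no filter 11195, the stricter filter 10338, recovered whole reads 10675 and the Y-linked covariate 10427. Without each library in turn, 10294 to 10663 genes changed, 5316 to 5539 higher and 4925 to 5150 lower, with 2557 to 2668 at least 2-fold, 10 to 14 lists by camera and 24 to 27 list means by the exact test. Among 143 single genes, those of the rule and those chosen later, 3219 comparisons over all alternatives kept call and direction, 22 gained a call, 10 lost it and 3 (Col1a2) reversed, and among lists 723 kept it, 64 gained and 24 lost it; the cause was not tested. The replicate block gave 10392 genes and called supporting cells (0.0475), osteoclasts (0.0349) and pericytes (0.0454) but not fibrillar collagens (0.0515). Same-numbered libraries deviated together with correlations of -0.077 to 0.108, and 1 of 5 fitted its own number best, so the numbers were not taken as pairs. The alternatives for a table with FPKM alone did not apply, no mitochondrially encoded genes were in the table, DESeq2 and the 1.2-fold test gave no list values, and the block and Y-linked fits gave no list-mean test. At this depth genes under the count filter were left out of the test per gene.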

Other observations

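The tests of the bone, hair cell and melanocyte patterns were chosen after the results were seen. Genes singled out in this part were likewise chosen after their values were seen. The ribosomal protein and imprinted gene lists followed from values of Eef1a1, Igf2, Plagl1 and Gpc3, with their tests set before the lists were measured. Eef1a1, which delivers aminoacyl-tRNA to the ribosome, rose from 4466 to 8016 CPM (log2 fold change 0.84), and 77 of 77 tested genes of cytosolic ribosomal proteins rose, with a median of 0.68. The median was 0.94 with library sizes alone and 0.65 with RLE factors, with all 77 higher in both. The hypothesis that these genes are higher as a group had a camera p of 1.1e-20 with the preset correlation and 0.105 with an estimated correlation, so it stays open.

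Imprinted genes of growth were picked out because the imprinted genes Igf2 and Plagl1 rose, and so did the X-linked growth gene Gpc3, from 7.89 to 64.5 CPM. Of 12 tested genes on a list that leaves out these 3, 8 rose and 4 fell, with a median of 0.93 (camera p = 0.0879, and p = 0.226 with an estimated correlation). Dlk1 rose from 0.705 to 9.22 CPM, Mest from 13.96 to 61.7 and Grb10 from 65.5 to 190 CPM, while Nnat fell from 207 to 46.6 and Slc38a4 from 25.5 to 8.62 CPM. The 12 genes thus did not share 1 direction. Whether the list as a whole is higher than other genes stays open, because camera does not pass with either correlation.

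The genes of the paired chains of type I collagen differed. Col1a1 fell by 3.89 on the log2 scale, from 361 ± 117 to 24.4 ± 8.29 CPM (SD, n = 5 each). Col1a2 had -0.08 (edgeR adjusted p = 0.181), at 6228 ± 309 and 5879 ± 295 CPM. With library sizes alone Col1a2 had 0.18 (edgeR adjusted p = 0.00330), in a range of p from 0.00228 to 0.664 over the alternatives. Col1a1 thus lay far below Col1a2 in both groups. The cause was not tested, and an error in the counts of Col1a1 was not excluded. Labels give no sex. Reads of Y-linked genes were few or absent in euthyroid replicate 5 and in hypothyroid replicates 2 and 5. Sex may therefore not have been balanced between the groups. With a covariate of Y-linked genes 10427 genes changed. The middle level in hypothyroid replicate 3 was not explained. The Y-linked gene Ddx3y lay at 114, 133, 128, 141 and 0.4 CPM in euthyroid replicates 1 to 5 and at 115, 0, 72.3, 116 and 0 CPM in hypothyroid replicates 1 to 5, and Eif2s3y followed it, with 51.3 CPM in hypothyroid replicate 3 against 97.0 and 104.5 in replicates 1 and 4.

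Bone matrix genes were far lower in the hypothyroid pieces. If less bone was taken along, osteoclast genes should be lower too, and all 5 were, with a median of -1.26. Their fall was known when this prediction was chosen, so it is no independent support for carry-over. If bone cells were at an earlier stage, mature genes should fall further than early ones, and the mean of 6 mature genes minus that of 4 early genes was -4.96, with Bglap2 at its bound. This decides nothing, because 3 of the mature genes (Bglap, Bglap2 and Mepe) are among the decreases that prompted the test and the first 2 may share reads. Runx2, the early osteoblast regulator, did not pass (-0.08, adjusted p = 0.776). Carry-over of bone and a delay of bone may both contribute, and neither was decided here. A delay cannot be told apart from other changes of bone cells by genes picked for their decrease.

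Hair cell genes such as Ocm and Slc26a5 were at or near 0 in the hypothyroid pieces. Genes that hair cells express from early stages, Pou4f3, Gfi1, Chrna9 and Lhx3, summed to 3.42 CPM in euthyroid libraries (lowest 1.92) and 0.142 CPM in hypothyroid libraries (highest 0.190, n = 5 each), a ratio of 24.1 without overlap (exact permutation p = 0.00794, the smallest possible). All 4 lie under the count filter and 3 of them belong to the list whose fall prompted the test, so the ratio decides nothing. More organ of Corti in the euthyroid pieces may be the source, and so may hair cells at an earlier stage in the hypothyroid pieces. Otof and Espn fell only 2.36-fold and 1.60-fold, and Myo7a rose (log2 fold change 1.30). Tmc1 did not pass (adjusted p = 0.0804), except without euthyroid replicate 2 (0.0272) or 3 (0.0381) or hypothyroid replicate 2 (0.0444). A lower share of hair cells alone leaves the rise of Myo7a unexplained unless other cells express it, and a loss of hair cells in the animals was not tested.

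Melanocyte genes of the stria were higher in the hypothyroid pieces. More stria would raise marginal cell genes as much. The intermediate list gained 0.88 on the marginal list (log2, -0.474 ± 0.061 against 0.408 ± 0.096, SD, n = 5 each, exact permutation p = 0.00794). The values of both lists were known when this comparison was chosen, and the intermediate list was picked for its rise. The gap therefore does not decide whether more stria was taken along. The lowest of the 5 hypothyroid means of the intermediate list lay 0.61 above the highest euthyroid mean. A single library therefore does not account for the rise of that list. Kcnj10, a member of the intermediate list, went the other way (log2 fold change -2.48). More melanocytes or more pigment gene expression in hypothyroid mice may remain as a hypothesis that was not tested. A different share of pigmented cells in the dissection was not tested either.

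Other groupings of the 10 libraries bear on the main counts. Among 100 of the 126 splits into 5 and 5, the real one gave 10667 changed genes, 5603 higher, 5064 lower and 2551 changed at least 2-fold. Only 1 split of 100, the real one, had counts as large, and the highest count of the other splits was 1. Every other split mixes the groups, so the difference between them widens the spread within each set and few calls can follow. The splits also take the libraries as independent, which the labels do not state. They therefore show that the libraries part by group, but do not exclude chance or a litter effect. For the number of lists called by camera, 15 of 100 splits gave 11 or more, and the highest other split gave 15. Chance cannot be excluded for that number either.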
